A study of Rattus norvegicus with 12 samples.

How the data were processed

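RNA was sequenced from 12 mitochondrial preparations of rat skeletal muscle, 3 for each of 4 isolation and treatment protocols. Per the labels' protocols, hindlimb muscle of a single animal was homogenised and pooled, and mitochondria were isolated from separate aliquots by differential centrifugation or by magnetic-bead immunoprecipitation. RNA was extracted with on-column DNase I treatment, and ribosomal RNA-depleted libraries were made with a Zymo-Seq RiboFree kit from 6.3 ng of RNA of crude mitochondria or 40 ng of the other preparations. Per the submitters' processing notes, reads were processed with FastQC 0.74, cutadapt 4.6, STAR 2.7.11a and HTSeq against mRatBN7.2. The annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. The deposited table holds whole-number read counts per Ensembl gene, not normalised, per the file headers and values. It covers 30560 genes, of which 24045 have a name and 6515 do not. Gene positions, lengths and GC content were not used here.

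Libraries were grouped by their titles and the series design. For crude mitochondria the source and tissue labels name immunoprecipitation while the title and the design text name crude mitochondria, and the latter were followed. Column names were matched to the labels' library descriptions, and 0 columns of other samples were present. Total counts ranged from 3325430 to 7123045 per library. Gene classes came from the deposited names and, for 17175 of the 21599 symbols that occur once, from a RefSeq gene table of assembly GRCr8, used for names and biotypes only. It marked 16618 nuclear genes as protein-coding. Shares of counts are percentages of all gene counts of a library. PCR copies are not independent molecules, and the 12 libraries are aliquots of 1 homogenate, so standard errors and p-values cover only the spread between these libraries.

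Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with TMM scaling on all 12 libraries in 1 model of 4 groups, with contrasts for IP_RNase against crude_RNase, IP_RNase_ProK against IP_RNase, mitoplast_RNase against IP_RNase, and mitoplast_RNase against IP_RNase_ProK. Genes were kept by filterByExpr with a minimum count of 10, which left 26483 genes (86.7%). P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05, and the common biological coefficient of variation was 0.0644. CPM values are scaled to effective library sizes. The SE is that of the log2 fold change, taken as its absolute value divided by the square root of the quasi-likelihood F. That F uses dispersions moderated over all genes, so the SE can be smaller than the spread of a gene's own libraries implies. TMM factors were 0.525 to 0.679 in crude_RNase and 1.12 to 1.23 in the other groups. The first principal component of log2 CPM held 52.9% of the variance and separated crude_RNase from the rest, and the second held 11.0%. Mitochondrial shares were compared by a two-sided exact permutation test with SciPy 1.17.1.

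Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. The 23 lists were mitochondrial mRNA, mitochondrial rRNA and tRNA, nuclear oxidative phosphorylation, cytosolic and mitochondrial ribosomal proteins, sarcomere, sarcoplasmic reticulum and T-tubule, glycolysis, tricarboxylic acid cycle and fatty acid oxidation, mitochondrial import and outer membrane, nuclear-retained noncoding RNA, small nucleolar and Cajal body RNA, noncoding RNA reported in mitochondria in earlier work, cytosolic small noncoding RNA, matrix and fibroblast, endothelial, smooth muscle and pericyte, erythroid, macrophage and leukocyte, adipocyte, Schwann cell and nerve, satellite cell, and endoplasmic reticulum chaperones and translocon. The glycolysis list also held Ckm and the list of the tricarboxylic acid cycle Ckmt2, the creatine kinases. Skeletal muscle itself also expresses some members of the non-muscle lists. The tests, these lists, the alternatives other than those named below and the rule for naming genes were chosen before the data were examined. The rule took, per comparison, the 8 highest and 8 lowest fold changes among genes past the threshold with a mean of at least 50 counts, separate CPM ranges and a proper symbol. It added up to 4 members of each list with the smallest p, the 13 mitochondrial mRNAs, both mitochondrial rRNAs, and Rmrp, Rpph1, Rn7sk, Rn7sl1, Malat1 and Neat1 where measured. The 2 most counted genes of the mitochondrial rRNA and tRNA list were taken as these rRNAs. A separate range in 3 against 3 libraries arises by chance for 10% of unchanged genes. Rmrp, Rn7sk, Malat1 and Neat1 were not analysed here, and some genes that the rule took are not reported here.

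The alternatives were DESeq2 1.42.0, edgeR with DESeq2 size factors, library size alone, scaling on the summed mitochondrial mRNAs, nuclear genes only, no filter, a minimum count of 50, fits of the 6 compared libraries, the replicate number as a block, a test against a log2 fold change of 1, other denominators of the mitochondrial share, and leaving out each library. Scaling on the summed olfactory receptor genes, the olfactory receptor list and leaving out crude_RNase 2 with IP_RNase 3 were added after the data were seen. The edgeR and camera procedures were tested on simulated data made from the real means and library sizes. The 200 changed genes were drawn from those above the median mean CPM. In each of the 4 comparisons edgeR recovered 92.5% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 5, 10, 8 and 15 false calls among 200, 205, 203 and 210, in 26251, 26250, 26262 and 26287 genes in the order given above. In each comparison camera called a list of 50 genes moved by 0.5 on the log2 scale and 0 of 20 unmoved lists, in 26278, 26273, 26281 and 26270 genes. The moved list was also drawn from above the median, and genes were simulated independently. The recovery rates therefore do not cover genes below the median, and the list result does not cover lists of correlated genes. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.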

Results

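The libraries were made to compare ways of purifying mitochondria from skeletal muscle for RNA profiling, and to learn which noncoding RNAs of the nuclear genome are found with them. Hindlimb muscle of 1 male Wistar Kyoto rat aged 14 weeks was homogenised and pooled, and separate aliquots of that homogenate gave 12 libraries in 4 groups of 3. The crude_RNase group held mitochondria pelleted by differential centrifugation, and the IP_RNase group held mitochondria captured with antibody-coated magnetic beads. The IP_RNase_ProK group had also received proteinase K, a protease that digests proteins exposed on the organelle surface. The mitoplast_RNase group held mitoplasts, which are mitochondria stripped of their outer membrane, prepared from the immunoprecipitated organelles. All 4 groups had received RNase A, an enzyme that degrades accessible single-stranded RNA. The counts summed to between 6583452 and 7123045 per crude_RNase library and to between 3325430 and 4563254 per library in the other 3 groups. Every replicate pair differed by more than sampling noise, with a chi-square of 1.25 to 12.96 per degree of freedom. Because all aliquots came from 1 animal, errors and p-values measure only the spread between these samples, which may be technical.

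Counts were found in nearly every gene of every library. Between 95.8% and 96.7% of the 30560 genes had at least 1 count, and so did 98.9% to 99.3% of the 1191 olfactory receptor genes, odorant sensors of the nasal epithelium that skeletal muscle does not normally transcribe. The median olfactory receptor gene had 30 to 49 counts per library, against 63 to 97 for the median nuclear gene. Olfactory receptor genes took 0.723% ± 0.0578 of the counts in crude_RNase and 1.71% ± 0.136 in IP_RNase, 1.67% ± 0.0128 in IP_RNase_ProK and 1.65% ± 0.0559 in mitoplast_RNase (SD, n = 3 each). Fold changes of weakly counted genes were therefore measured on top of this level.

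The mitochondrial chromosome, which encodes 13 respiratory chain subunits along with its own rRNAs and tRNAs, took a larger share of the counts in each crude library than in any other. Its 37 genes took 49.5% ± 7.18 of all counts in crude_RNase, 6.51% ± 3.95 in IP_RNase, 2.75% ± 0.653 in IP_RNase_ProK and 3.28% ± 0.719 in mitoplast_RNase (SD, n = 3 each). The 13 mRNAs alone took 25.7% ± 2.97, 4.0% ± 1.52, 1.76% ± 0.294 and 1.74% ± 0.207, and the 24 rRNA and tRNA genes 23.8% ± 5.25, 2.51% ± 2.47, 0.991% ± 0.375 and 1.54% ± 0.524, in the same order. Nuclear protein-coding genes took 39.4% ± 6.06 in crude_RNase and 74.5% ± 3.11, 78.2% ± 0.604 and 77.9% ± 0.879 in the other groups. Nuclear rRNA genes took 2.22% ± 0.0745 in crude_RNase and 0.0778% ± 0.0112 in IP_RNase, and genes of the signal recognition particle RNA, which guides ribosomes to the endoplasmic reticulum, took 0.152% ± 0.0256 and 0.0121% ± 0.00187. The mitochondrial share differed by -43.0 percentage points between IP_RNase and crude_RNase, without overlap between the 6 libraries (two-sided exact permutation p = 0.1, adjusted p = 0.4 over 4 comparisons). The difference was -3.77 points between IP_RNase_ProK and IP_RNase (exact p = 0.2, adjusted p = 0.4), -3.23 between mitoplast_RNase and IP_RNase (exact p = 0.3, adjusted p = 0.4) and 0.536 between mitoplast_RNase and IP_RNase_ProK (exact p = 0.4, adjusted p = 0.4). With 3 libraries against 3 the smallest p this test allows is 0.1. The difference from IP_RNase rested in part on IP_RNase 3, at 10.9%: without it the values were -1.56 and -1.02 points, and the difference between mitoplast_RNase and IP_RNase_ProK was 0.919 points without mitoplast_RNase 3 and 0.192 without IP_RNase_ProK 1.

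**Figure D1:**
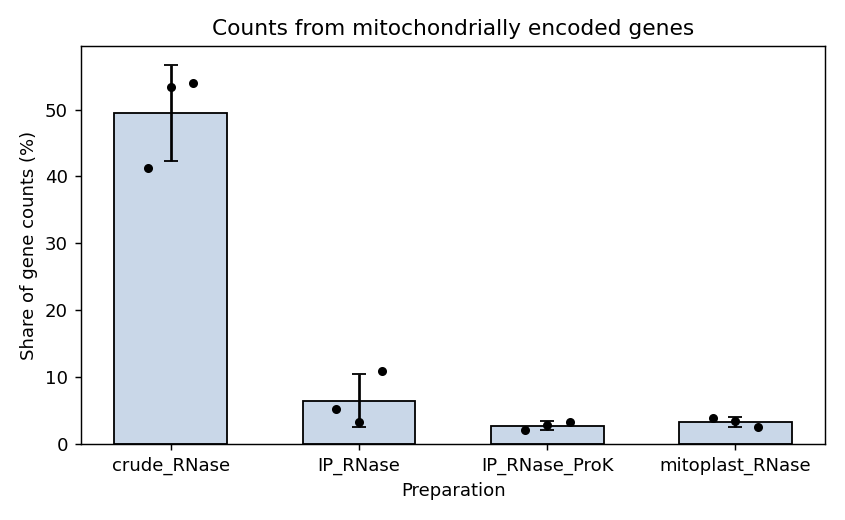
Share of all gene counts (percent, y axis) from the 37 mitochondrially encoded genes in the 4 preparations, with bars for group means, error bars for the SD and points for the 3 libraries. The crude_RNase libraries lie between 41.2% and 54.0%, above the 2.06% to 10.9% of the other 9.

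The first comparison asked what differed between bead-captured and centrifuged mitochondria. Messenger RNAs of the contractile apparatus and of muscle energy supply were far lower after bead capture. Acta1 (ENSRNOG00000017786), skeletal muscle actin, had 27.1 ± 8.71 CPM (counts scaled to a library size of 1e+06) in IP_RNase and 1755 ± 194 in crude_RNase (SD, n = 3 each), a log2 fold change of -6.01 ± 0.122 (SE; edgeR quasi-likelihood adjusted p = 5.41e-41). Mylpf, the fast-muscle regulatory light chain of myosin, was at -4.67 ± 0.109, and the fast troponins Tnnc2 and Tnni2 were at -4.41 ± 0.104 and -3.69 ± 0.0873. Of 40 sarcomere genes tested, 39 fell and 1 did not pass, with a median of -1.08, which was -0.02 under library size scaling and 2.82 when counts were scaled on the mitochondrial mRNAs. Of 19 genes of the glycolysis list, which also holds muscle creatine kinase and genes of glycogen breakdown, 15 fell and 4 did not pass. Among those that fell were Pygm, muscle glycogen phosphorylase, at -2.71 ± 0.0835, and the creatine kinase Ckm at -3.50 ± 0.0958, with a list median of -1.15 that became 2.68 under mitochondrial mRNA scaling. Among 22 genes of the sarcoplasmic reticulum and T-tubule, the membranes of calcium release, 16 fell, such as the calcium store protein Casq1 at -1.75 ± 0.0862, with a median of -0.50 that became 0.52 by library size and 3.3 by mitochondrial mRNA scaling. Adjusted over the list alone, the counts were 39 of 40, 16 of 19 and 18 of 22. The camera adjusted p-values of these 3 lists were 2.77e-117, 4.73e-54 and 6.2e-23. With an estimated correlation they were 0.00011, 8.48e-06 and 0.00014. In IP_RNase some of these genes stood near the median nuclear gene, which had 70 to 76 counts. Mylpf had 80, 51 and 72 raw counts there and Ckm 87, 100 and 95, while Pygm had 225, 206 and 247. Fold changes in this comparison may be limited by that level, so their sizes need not rank how far genes or lists were depleted.

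RNAs encoded in the mitochondria fell as well. Mt-co1 (ENSRNOG00000034234), a catalytic subunit of cytochrome c oxidase, had 5135 ± 2620 CPM in IP_RNase and 84599 ± 18871 in crude_RNase (SD, n = 3 each), a log2 fold change of -4.04 ± 0.259 (edgeR adjusted p = 6.75e-19). All 13 mitochondrial mRNAs fell over all genes and adjusted over the list alone, from -4.04 to -2.67 with a median of -3.69, which was -2.65 by library size, -3.88 on olfactory receptor genes and 0.02, by construction near 0, on the mitochondrial mRNAs themselves (camera adjusted p = 7.31e-84). The smallest change was that of Mt-atp8, an ATP synthase subunit, at -2.67 ± 0.139. Mt-nd6, a complex I subunit read from the other strand than the rest, was at -3.19 ± 0.188, and since the strand setting of the counting is not given in the sources used here, its reads may include those of the opposite strand. The 4 measured genes of the mitochondrial rRNA and tRNA list fell, 4 also when adjusted over the list alone, with a median of -4.23 that stayed negative at -0.62 under mitochondrial mRNA scaling (camera adjusted p = 1.51e-15). ENSRNOG00000043866 and ENSRNOG00000030478, the 2 genes that held 99.6% to 99.9% of the list's counts and are not named as rRNAs in the deposited table, were at -4.35 ± 0.403 and -4.18 ± 0.409. Without IP_RNase 3 these values were -5.55 and -5.54.

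Some nuclear messages for mitochondrial proteins were lower too. Slc25a4, the muscle ADP/ATP carrier, was at -4.04 ± 0.105 and Atp5f1b, the catalytic ATP synthase subunit, at -2.71 ± 0.1 (edgeR adjusted p = 1.36e-36 and 2.03e-29). Of 72 nuclear genes of oxidative phosphorylation, 44 fell and 28 did not pass (53 fell when adjusted over the list alone), among them Cox4i1, a cytochrome c oxidase subunit, at -1.70 ± 0.107, and the median of -0.62 became 0.40 by library size and 3.19 by mitochondrial mRNA scaling. Of 35 genes in the list of the tricarboxylic acid cycle and fatty acid oxidation, which also holds mitochondrial creatine kinase, 22 fell (28 adjusted over the list alone), with that kinase, Ckmt2, at -1.40 ± 0.0903, and the median of -0.46 became 0.57 and 3.38 under those scalings. Of 35 genes of import and the outer membrane, 10 fell (20 adjusted over the list alone), including Vdac3, an outer membrane channel, at -1.20 ± 0.117, and the median of -0.29 became 0.74 and 3.53. Among 72 mitochondrial ribosomal proteins, 4 fell and 68 did not pass (5 fell adjusted over the list alone), such as Mrps21 at -0.82 ± 0.202, and the median of -0.15 became 0.88 and 3.66. The camera adjusted p-values of these 4 lists were 3.58e-38, 5.33e-22, 8.16e-13 and 0.00576.

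RNAs of the cytosolic translation machinery were among the most strongly reduced. Rn7sl1 (ENSRNOG00000065968), the RNA of the signal recognition particle, was at -7.40 ± 0.766 (edgeR adjusted p = 3.95e-11), with raw counts of 13, 7 and 9 in IP_RNase and 320, 122 and 3857 in crude_RNase, and without crude_RNase 3 the value was -4.52. Metazoa_SRP (ENSRNOG00000055825), a related copy, was at -6.29 ± 0.161, and at -7.21 without IP_RNase 3. Of 32 cytosolic small noncoding RNA genes 12 fell, 1 rose and 19 did not pass (13 and 1 adjusted over the list alone), with a mean of -1.56 and a median of -0.39 that became 0.62 by library size and 3.31 by mitochondrial mRNA scaling (camera adjusted p = 1.2e-11). Of 75 cytosolic ribosomal protein genes 66 fell and 9 did not pass (67 fell adjusted over the list alone), with a median of -1.69 that became 2.14 under mitochondrial mRNA scaling (camera adjusted p = 3.23e-152). Rps4x was at -3.91 ± 0.141, Rplp0 at -3.14 ± 0.0939 and Rps6 at -2.59 ± 0.102. The genes listed as 18S and 28S rRNA (ENSRNOG00000068307 and ENSRNOG00000064743), chosen after their values were seen, were at -6.57 ± 0.206 and -5.81 ± 0.205, the latter at -7.25 without IP_RNase 3. Reads of ribosomal protein, rRNA and signal recognition particle genes can be shared with near-identical copies, so the values of single copies are uncertain.

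Among noncoding RNAs reported in mitochondria, Rpph1 fell, and 5S_rRNA copies with fewer counts than the median olfactory receptor gene moved in both directions. Rpph1 (ENSRNOG00000054493), the RNA of the nuclear tRNA-processing enzyme RNase P, had 9.58 ± 5.31 CPM in IP_RNase and 337 ± 94.1 in crude_RNase (SD, n = 3 each), a log2 fold change of -5.12 ± 0.169 (edgeR adjusted p = 9.19e-32). Its raw counts in IP_RNase were 33, 22 and 68, against 37 to 44 for the median olfactory receptor gene, so the size of this change may be limited by that level. A 5S_rRNA copy (ENSRNOG00000064405), encoding the small RNA of the large ribosomal subunit, rose from 1.04 ± 0.339 to 7.21 ± 0.918 CPM, by 2.78 ± 0.409 (edgeR adjusted p = 6.89e-07). Copies of 5S_rRNA went both ways: ENSRNOG00000069035 rose from raw counts of 0 in each crude_RNase library to 5, 7 and 11 in IP_RNase (edgeR adjusted p = 0.000102), and ENSRNOG00000034597 fell from 4.47 ± 1.79 to 1.36 ± 0.653 CPM, by 1.74 ± 0.412 on the log2 scale (edgeR adjusted p = 0.00284), a call that ended without crude_RNase 1 or IP_RNase 3 (adjusted p = 0.0528 and 0.0501). Of 175 genes of this list in the deposited table, 16 could be tested. Of these, 2 rose, 2 fell and 12 did not pass, the same when adjusted over the list alone. The list did not pass (camera adjusted p = 0.636), with a median of 0.14 and a mean of 0.30, the median becoming -0.07 when scaled on the olfactory receptor genes. The U3 copy ENSRNOG00000068470, a small nucleolar RNA of rRNA processing, was at 0.85 ± 0.267 (edgeR adjusted p = 0.0401), and the call ended without crude_RNase 1, crude_RNase 2, IP_RNase 1 or IP_RNase 2 (adjusted p = 0.0912, 0.0879, 0.321 and 0.07) and with DESeq2 (adjusted p = 0.131). Of 85 small nucleolar and Cajal body RNAs 3 rose (1 adjusted over the list alone), with a list median of 0.09 that became -0.12 under the same scaling (camera adjusted p = 0.12). Of 204 nuclear-retained noncoding RNAs 1 rose and 1 fell (0 and 0 adjusted over the list alone), with a median of 0.05 that became -0.17 (camera adjusted p = 0.266). The members of that list with the smallest p were copies of the small nuclear RNAs U1, U4 and U6. Their means were 8.67 to 20.8 counts over the 6 libraries, fewer than the median olfactory receptor gene had. Few calls in that list therefore do not show that nuclear-retained RNA was unaffected. Rmrp, Rn7sk, Malat1 and Neat1 were not analysed here.

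Matrix genes and some non-muscle markers were lower after bead capture, while markers of most other cell types did not pass. Of 23 extracellular matrix and fibroblast genes, 17 fell (20 adjusted over the list alone), among them the fibrillar collagens Col3a1 at -3.26 ± 0.083 and Col1a1 at -2.11 ± 0.074 and the matrix glycoprotein Sparc at -2.64 ± 0.0873, and the median of -0.59 became 0.45 by library size and 3.27 by mitochondrial mRNA scaling. Of 25 endoplasmic reticulum chaperone and translocon genes, 6 fell (9 adjusted over the list alone), such as the chaperone Hspa5 at -0.80 ± 0.108, with a median of -0.24 that became 0.79 and 3.52 under those scalings. Of 17 macrophage and leukocyte genes, 6 fell, 6 also adjusted over the list alone, such as Cd74, the invariant chain of antigen presentation, at -0.71 ± 0.104, with a median of -0.15 that became 0.89 and 3.70. The camera adjusted p-values of these 3 lists were 3.58e-43, 1.65e-07 and 0.0022. Among 12 adipocyte genes 3 fell (3 fell and 1 rose adjusted over the list alone), including Plin4, a lipid droplet protein, at -0.63 ± 0.105 (camera adjusted p = 0.117, and 0.0425 without crude_RNase 3). In the endothelial (15 tested), erythroid (9), satellite cell (8) and smooth muscle and pericyte (12) lists 1 gene each fell, 1 each also when adjusted over the list alone, and 0 of 12 Schwann cell and nerve genes were called by edgeR on either adjustment (2 at an unadjusted p under 0.05, 0 by DESeq2). Those genes were the fatty acid carrier Fabp4 at -1.09 ± 0.142, the haemoglobin chain Hba-a2 at -0.58 ± 0.0997, the proteoglycan Sdc4 at -0.65 ± 0.135 and the myosin kinase Mylk at -0.35 ± 0.0749. The camera adjusted p-values of these 5 lists were 0.394, 0.711, 0.6, 0.159 and 0.636, and the erythroid list had a median of 0.09 and a mean of 0.02 but a test direction below 0.

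**Figure D2:**
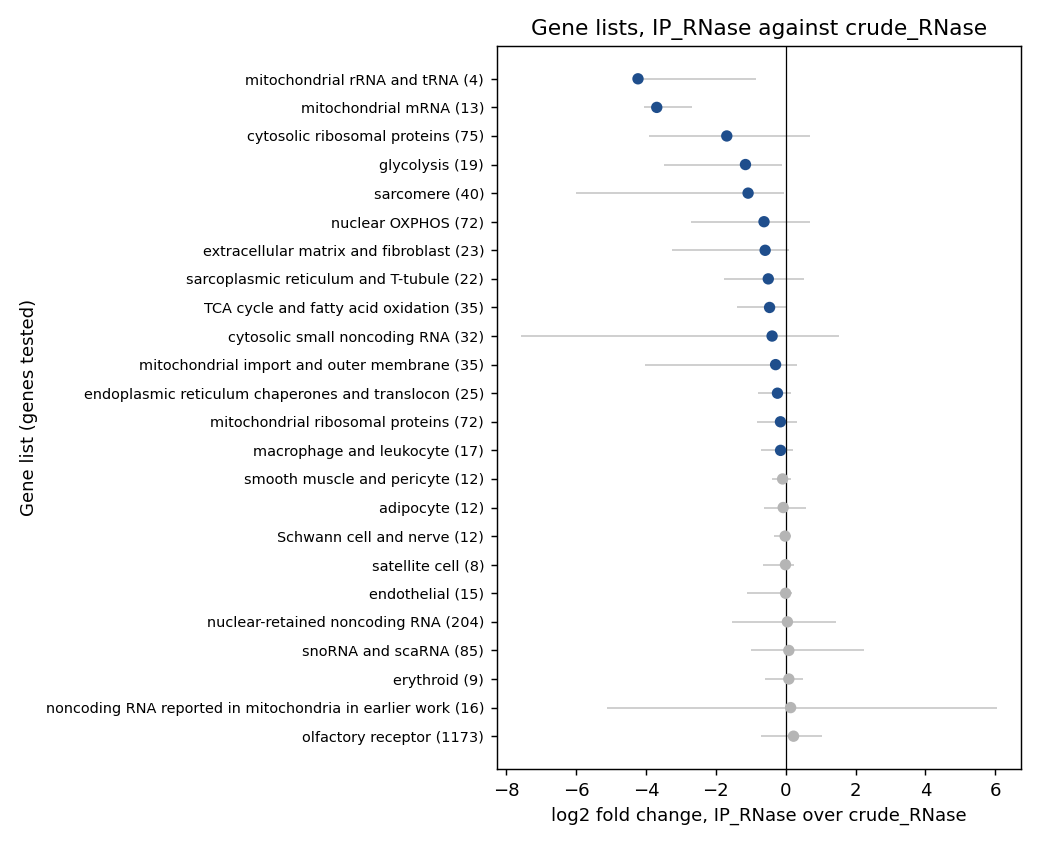
Log2 fold change of IP_RNase against crude_RNase (x axis) for each gene list, with a dot for the median, a grey line for the range of the members, the number of genes tested in brackets, and blue for lists past the camera test. Medians of the lists that passed lie between -4.23 and -0.15 under TMM scaling. Library size and mitochondrial mRNA scaling shift the median of all genes by 1.03 and 3.81, so the sign of a median depends on the scaling.

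In all, 1684 of 26483 genes passed between IP_RNase and crude_RNase, 335 higher and 1349 lower (edgeR quasi-likelihood, Benjamini-Hochberg), with 43 higher and 337 lower by more than 1 on the log2 scale. Few of the rises were large: Olr462, an olfactory receptor, was at 0.76 ± 0.169 (edgeR adjusted p = 0.00119), and belongs to a family with similar copies. The olfactory receptor genes, a list added after the data were seen, had a median of 0.22 with 47 of 1173 higher and 0 lower (7 and 0 adjusted over the list alone), and a median of 0.01 when scaled on themselves (camera unadjusted p = 9.175e-11, and 0.0476 with an estimated correlation). All 14 lists past the camera test held with an estimated correlation, with larger adjusted p-values, such as 0.000972 for the mitochondrial mRNAs (7.31e-84 with the preset one). The direction of the calls was relative to the scaling. Library size alone gave 25094 higher and 189 lower genes, the mitochondrial mRNAs 26435 and 14, and the olfactory receptor genes 58 and 4414, with shifts of the all-gene median of 1.03, 3.81 and -0.21. Input RNA was 6.3 ng for crude mitochondria and 40 ng for the other preparations, so input and isolation method were confounded.

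The second comparison asked what proteinase K changed on immunoprecipitated mitochondria. Mitochondrial mRNAs were lower after the protease, and few nuclear genes passed. The median nuclear gene had 70 to 97 counts per library in both groups, against 37 to 49 for the median olfactory receptor gene. Few nuclear calls therefore do not show that nuclear RNA was unaffected. Mt-co3 (ENSRNOG00000030700), a cytochrome c oxidase subunit, had 1073 ± 224 CPM in IP_RNase_ProK and 2997 ± 1207 in IP_RNase (SD, n = 3 each), a log2 fold change of -1.48 ± 0.199 (edgeR adjusted p = 2.94e-06). Mt-co1 was at -1.33 ± 0.234 (edgeR adjusted p = 0.000779, and 0.0506 without IP_RNase_ProK 1) and Mt-nd6 at -1.21 ± 0.178 (adjusted p = 2.46e-05). Mt-atp8 was at -0.95 ± 0.204 (edgeR adjusted p = 0.0204), and its call ended without IP_RNase 1, IP_RNase 3, IP_RNase_ProK 1 or IP_RNase_ProK 3 (adjusted p = 0.0521, 0.602, 0.243 and 0.139). All 13 mRNAs fell, over all genes and adjusted over the list alone, from -1.48 to -0.95 with a median of -1.21, which was -1.14 by library size, -1.12 on the olfactory receptor genes and 0.04 on the mitochondrial mRNAs themselves. The list's camera adjusted p was 6.7e-59, and 0.0271 with an estimated correlation. The correlation estimated between these 13 mRNAs was 0.96 in each comparison, so their calls are not 13 independent results. Each of 11 of the 13 kept its call in all 12 fits that left out 1 library.

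The mitochondrial rRNA and tRNA list was also lower, with a median of -1.33 that became 0.07 when scaled on the mitochondrial mRNAs, and 0 of 4 genes called by edgeR over all genes (3 adjusted over the list alone, 3 at an unadjusted p under 0.05, 0 by DESeq2), at a camera adjusted p of 6.07e-05. It was not past the threshold with an estimated correlation (adjusted p = 0.424 with an estimated correlation) or without IP_RNase 3 (camera adjusted p = 0.439, median -0.18). ENSRNOG00000043866 was at -1.51 ± 0.359 and ENSRNOG00000030478 at -1.35 ± 0.366 (edgeR adjusted p = 0.0654 and 0.155), and without IP_RNase 3 at -0.31 and 0.01. Both passed without crude_RNase 1 (edgeR adjusted p = 0.00757 and 0.0339), crude_RNase 2 (0.0137 and 0.0457) or IP_RNase 2 (7.24e-05 and 0.000569), and the first also without IP_RNase 1 (0.0108). No other of the 23 lists passed. The added olfactory receptor list, kept out of the adjustment, was lower (median -0.11, camera unadjusted p = 1.857e-05, and 0.161 with an estimated correlation), with 0 of 1173 genes called by edgeR over all genes or adjusted over the list alone, 87 at an unadjusted p under 0.05 and 0 by DESeq2. Of the 23, the cytosolic ribosomal proteins came nearest (median 0.05, camera adjusted p = 0.0687) and passed without IP_RNase 1, IP_RNase 3, IP_RNase_ProK 3, mitoplast_RNase 1 or mitoplast_RNase 3 (adjusted p = 0.037, 0.0475, 0.045, 0.0432 and 0.0408). The cytosolic small noncoding RNAs (median -0.18, and 0.98 when scaled on the mitochondrial mRNAs, camera adjusted p = 0.289) passed without IP_RNase 1 (adjusted p = 0.037).

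Of the noncoding RNAs, Rpph1 was at -0.65 ± 0.304 and did not pass (edgeR adjusted p = 0.532). It had 34, 40 and 17 raw counts in IP_RNase_ProK, against 40 to 49 for the median olfactory receptor gene there. U3 (ENSRNOG00000068470) fell by 1.16 ± 0.265 on the log2 scale (edgeR adjusted p = 0.0475), a call that ended without IP_RNase 1, IP_RNase 2, IP_RNase_ProK 1, IP_RNase_ProK 3, mitoplast_RNase 1 or mitoplast_RNase 2 (adjusted p = 0.56, 0.0919, 0.121, 0.35, 0.0584 and 0.0615). A 5_8S_rRNA copy (ENSRNOG00000070263), one of the RNAs of the large ribosomal subunit, was at 0.78 ± 0.138 (edgeR adjusted p = 0.000886, 0.0521 without IP_RNase 1 and 0.0716 without IP_RNase_ProK 2). Igf2, a fetal growth factor, was at 0.46 ± 0.0967 (edgeR adjusted p = 0.0187), and not called without IP_RNase 1, 2 or 3 or without IP_RNase_ProK 1 or 2 (adjusted p = 0.126, 0.0857, 0.107, 0.262 and 0.152). Coasy, the enzyme of the last steps of coenzyme A synthesis, was at 0.53 ± 0.113 (edgeR adjusted p = 0.0187), and not called without IP_RNase 1 or IP_RNase_ProK 1, 2 or 3 (adjusted p = 0.434, 0.0506, 0.248 and 0.0655). Of the 8 higher genes, 0 kept the edgeR call in all 12 fits that left out 1 library. Among the lower genes were 12 without a name, of which 9 kept it. Examples chosen after their values were seen were ENSRNOG00000069946 at -1.10 ± 0.0973 and ENSRNOG00000068515 at -1.30 ± 0.134 (edgeR adjusted p = 3.69e-11 and 4.07e-09).

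In all, 37 genes passed between IP_RNase_ProK and IP_RNase, 8 higher and 29 lower, of which 20, all lower, changed by more than 1 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg). Under library size scaling 1 was higher and 22 lower, and under mitochondrial mRNA scaling, which shifted the all-gene median by 1.13, 24889 were higher and 1 lower. A fit of the 6 libraries alone called 143 genes, 69 higher and 74 lower. The count was 88 without crude_RNase 1, 77 without crude_RNase 2, 24 without IP_RNase 1 and 24 without IP_RNase_ProK 1.

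The third comparison asked what removing the outer membrane changed. Mitochondrial mRNAs were again lower than in the immunoprecipitated mitochondria. Mt-co3 had 1038 ± 115 CPM in mitoplast_RNase and 2997 ± 1207 in IP_RNase (SD, n = 3 each), a log2 fold change of -1.53 ± 0.199 (edgeR adjusted p = 1.46e-06). Mt-nd3, a complex I subunit, was at -1.35 ± 0.164 (edgeR adjusted p = 2.45e-07). Mt-co1 was at -1.24 ± 0.233 (edgeR adjusted p = 0.00236), but at -0.76 without IP_RNase 3 (adjusted p = 0.0914), with adjusted p = 0.0879 without mitoplast_RNase 3 and DESeq2 adjusted p = 0.0869. Mt-atp6, an ATP synthase subunit, was at -1.11 ± 0.194 (edgeR adjusted p = 0.000615), and not called without IP_RNase 3 (-0.71, adjusted p = 0.0646), without mitoplast_RNase 3 (adjusted p = 0.0505) or with DESeq2 (adjusted p = 0.0893). Mt-atp8 was at -0.84 ± 0.201 and did not pass (edgeR adjusted p = 0.0632), though it did without crude_RNase 1, crude_RNase 2 or IP_RNase 2 (adjusted p = 0.0125, 0.00953 and 0.000196). Of the 13 mRNAs, 12 fell over all genes and 13 adjusted over the list alone, with a median of -1.24 that was -1.17 by library size, -1.15 on the olfactory receptor genes and 0.02 on the mitochondrial mRNAs themselves. The list's camera adjusted p was 1.17e-58, and 0.0275 with an estimated correlation.

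Mitochondrial rRNA and tRNA genes had a median of -0.78, with 0 of 4 called by edgeR over all genes (2 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2), and the median became 0.67 when scaled on the mitochondrial mRNAs and 0.09 without IP_RNase 3. Their camera adjusted p was 0.00961, with adjusted p = 0.424 with an estimated correlation, 0.942 without IP_RNase 3 and 0.133 without mitoplast_RNase 3. ENSRNOG00000043866 was at -0.87 ± 0.354 and ENSRNOG00000030478 at -0.69 ± 0.361 (edgeR adjusted p = 0.441 and 0.576), at 0.33 and 0.67 without IP_RNase 3, and the first passed without IP_RNase 2 (adjusted p = 0.0494). Genes of the sarcoplasmic reticulum and T-tubule were slightly higher in mitoplasts as a list (median 0.08, and positive under each scaling run), with 0 of 22 called by edgeR over all genes or adjusted over the list alone, 6 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.0172). That list did not pass with an estimated correlation (adjusted p = 0.424 with an estimated correlation) or without IP_RNase 1, IP_RNase 2 or mitoplast_RNase 3 (camera adjusted p = 0.08, 0.0929 and 0.133). Its members with the smallest p included Stac3, a coupling adaptor, at 0.35 ± 0.122, and Ryr1, the calcium release channel, at 0.25 ± 0.0913 (edgeR adjusted p = 0.374 and 0.402). Sarcomere genes (median 0.05, camera adjusted p = 0.0709) passed without crude_RNase 2, IP_RNase 3, mitoplast_RNase 1 or mitoplast_RNase 3 (adjusted p = 0.0226, 0.00509, 0.0279 and 0.00498), and cytosolic ribosomal proteins (camera adjusted p = 0.0709) passed without mitoplast_RNase 2 (adjusted p = 0.00828). The added olfactory receptor list was lower (median -0.11, camera unadjusted p = 6.228e-06, and 0.142 with an estimated correlation), with 0 of 1173 genes called by edgeR over all genes or adjusted over the list alone, 86 at an unadjusted p under 0.05 and 0 by DESeq2.

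Among noncoding RNAs, Rpph1 was at 0.27 ± 0.267 in mitoplasts (edgeR adjusted p = 0.795). It had 44, 76 and 49 raw counts there, against 38 to 46 for the median olfactory receptor gene. The 5S_rRNA copy ENSRNOG00000064405 had 2.04 ± 1.32 CPM in mitoplast_RNase and 7.21 ± 0.918 in IP_RNase (SD, n = 3 each), a log2 fold change of -1.78 ± 0.333 (edgeR adjusted p = 0.00215). Its call ended without mitoplast_RNase 1 or mitoplast_RNase 3 (edgeR adjusted p = 0.095 and 0.0642), and the value was -2.46 without mitoplast_RNase 2. The 5_8S_rRNA copy ENSRNOG00000070263 was at 0.83 ± 0.138 (edgeR adjusted p = 0.000293, and 0.0817 without mitoplast_RNase 3). Runx3, a transcription factor of lymphocytes and neurons, was at 0.51 ± 0.106 (edgeR adjusted p = 0.0104), and not called without IP_RNase 1 or 3 or mitoplast_RNase 2 or 3 (adjusted p = 0.243, 0.126, 0.123 and 0.0601). Amz1, a metallopeptidase, was at 0.51 ± 0.111 (edgeR adjusted p = 0.0212), and not called without IP_RNase 1 or 3 or mitoplast_RNase 1, 2 or 3 (adjusted p = 0.294, 0.158, 0.0835, 0.0707 and 0.205). Of the 6 higher genes, 0 kept the edgeR call in all 12 fits that left out 1 library, against 10 of the 12 mitochondrial mRNAs and 8 of 16 unnamed lower genes. The unnamed ENSRNOG00000069946 was at -1.15 ± 0.0979 and ENSRNOG00000068515 at -1.31 ± 0.135 (edgeR adjusted p = 8.47e-12 and 3.47e-09), both chosen after their values were seen.

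In all, 41 genes passed between mitoplast_RNase and IP_RNase, 6 higher and 35 lower, of which 1 higher and 21 lower changed by more than 1 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg). Under library size scaling 1 was higher and 27 lower, and under mitochondrial mRNA scaling, with an all-gene shift of 1.12, 24728 were higher and 0 lower. A fit of the 6 libraries alone called 115 genes, 42 higher and 73 lower. The count was 78 without crude_RNase 1, 73 without crude_RNase 2, 27 without IP_RNase 1 and 25 without mitoplast_RNase 3. The lower calls after proteinase K and in mitoplasts shared 23 genes, 12 of them mitochondrial mRNAs and 11 unnamed, against 0.0383 for independent lists. In 20 simulations of unchanged groups, with the same simulated IP_RNase libraries in both contrasts, the mean was 0.1 (at most 1). The simulations drew genes independently, without a shift common to many genes of a library. They therefore cannot tell whether such a shift gave the overlap. The higher calls shared 1, the 5_8S_rRNA copy, against 0.00181 for independent lists and a simulated mean of 0.15 (at most 1, as many as observed). The 3 shared control libraries cannot be split, so part or all of the overlap may come from them.

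**Figure D3:**
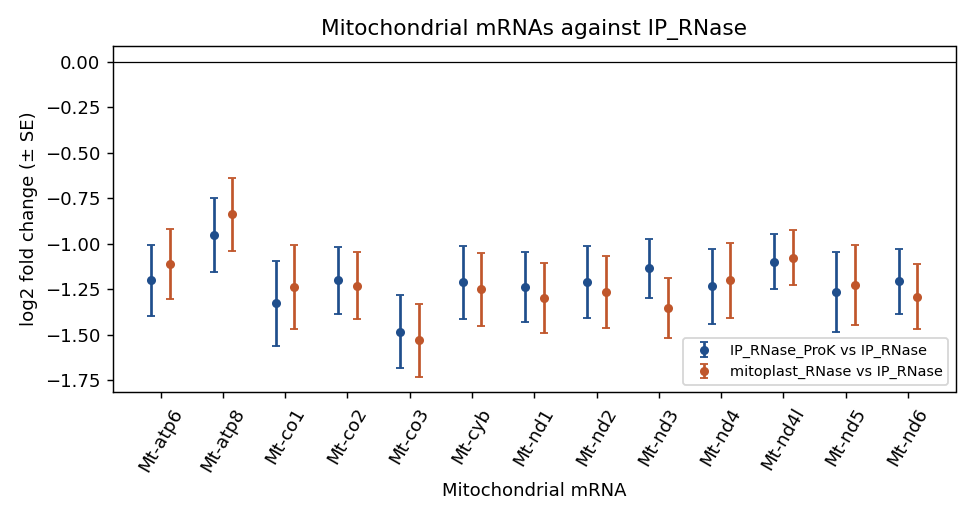
Log2 fold change (y axis, with SE as error bars) of the 13 mitochondrial mRNAs (x axis) against IP_RNase, in blue for IP_RNase_ProK and in orange for mitoplast_RNase, 3 libraries per group. Under TMM scaling all values lie below 0, between -1.53 and -0.84, and their medians are 0.04 and 0.02 when counts are scaled on the mitochondrial mRNAs.

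The last comparison set mitoplasts against proteinase K-treated mitochondria directly. Mitochondrial mRNAs did not pass: Mt-co1 was at 0.09 ± 0.23 and Mt-co3 at -0.05 ± 0.195, and the 13 ranged from -0.22 to 0.11 with a median of -0.03 (camera adjusted p = 0.966). Rpph1 was at 0.92 ± 0.284 and ENSRNOG00000043866 at 0.64 ± 0.353 (edgeR adjusted p = 1 for both). The sarcomere list was higher in mitoplasts, with a median of 0.06 that was positive under each scaling run, 0 of 40 genes called by edgeR over all genes, 2 adjusted over the list alone, 6 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.00012). It did not pass with an estimated correlation (adjusted p = 0.697 with an estimated correlation) or without mitoplast_RNase 2 (camera adjusted p = 0.182). Its members with the smallest p included Tnnt3, fast troponin T, at 0.50 ± 0.133, and Myh4, a fast myosin heavy chain, at 0.37 ± 0.104, while the giant spring protein Ttn was at 0.60 ± 0.276 (edgeR adjusted p = 1 for each). The cytosolic small noncoding RNAs (camera adjusted p = 0.0893) passed without IP_RNase 3 or IP_RNase_ProK 2 (adjusted p = 0.0155 and 0.0292), and the mitochondrial rRNA and tRNA list (camera adjusted p = 0.451) without mitoplast_RNase 3 (adjusted p = 0.0318).

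Of 26483 genes, 0 passed in this comparison with edgeR and 0 with DESeq2, and 741 had an unadjusted edgeR p under 0.05. The count was 2 without crude_RNase 1, crude_RNase 2 or IP_RNase 3 and 1 without mitoplast_RNase 3. A fit of the 6 libraries alone called 11 genes, all higher in mitoplasts, among them Ttn, Myh4, Tnnt3 and Rpph1 (edgeR adjusted p = 7.57e-07, 2.6e-05, 6.4e-05 and 0.0409). Each of these named genes had its highest raw count in mitoplast_RNase 2, such as 13134 for Ttn against 8262 and 6210 in the other mitoplast libraries. That fit was not repeated without mitoplast_RNase 2. Rpph1 had 44, 76 and 49 raw counts in mitoplast_RNase and 34, 40 and 17 in IP_RNase_ProK, near the median olfactory receptor gene. The median nuclear count lay near that of the olfactory receptor genes, so the 0 calls of the full fit do not show equal nuclear RNA. Across the last 3 comparisons the median and mean of a list that did not pass differed in sign for some lists: endothelial genes after proteinase K (0.03 and -0.01) and in mitoplasts against IP_RNase (0.02 and -0.02), nuclear oxidative phosphorylation in the latter (0.01 and -0.01), and noncoding RNAs reported in mitochondria between mitoplasts and proteinase K (-0.10 and 0.04). In further lists 1 of these values or the test direction lay on the other side of 0 with both within 0.04 of 0: matrix, glycolysis and tricarboxylic acid cycle genes after proteinase K, and cytosolic ribosomal protein, endoplasmic reticulum, endothelial, macrophage, import, smooth muscle and small nucleolar RNA genes in the last comparison.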

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

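Scaling on the olfactory receptor genes and leaving out crude_RNase 2 with IP_RNase 3 were chosen only after the result was seen. Library size, mitochondrial mRNA and olfactory receptor scaling shift the median of all genes, though not each gene equally, so a changed sign of a gene under them need not be a change relative to other genes. Under these 3 scalings 165 values of named genes were counted as unchanged, meaning called in the same direction in both fits or called in neither. Of the rest, 25 lost their call, 3 gained one, and 38 changed sign while called in at least 1 of the fits. Under the alternatives other than these and leaving out 1 library the numbers were 594, 45, 13 and 0. For lists they were 73, 3, 9 and 7 under mitochondrial mRNA scaling and 428, 5, 6 and 1 under the others. Over the fits without 1 library the numbers were 869, 44, 11 and 0 for genes and 1082, 6, 15 and 1 for lists. Values called in neither fit could also change sign. For example, ENSRNOG00000030478 in mitoplasts against IP_RNase went from -0.69 to 0.67 without IP_RNase 3. DESeq2 called 1128, 35, 33 and 0 genes in the 4 comparisons (IP_RNase against crude_RNase, IP_RNase_ProK and mitoplast_RNase against IP_RNase, and mitoplast_RNase against IP_RNase_ProK), of which 1122, 22, 21 and 0 were also called by edgeR. The medians of 30 to 49 counts in genes not normally transcribed in muscle limit what depth can show for weakly expressed genes.

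Library size alone called 25283 and 23 genes in the first and second comparison. Scaling on the mitochondrial mRNAs called 26449, 24890, 24728 and 1 genes, and 6, 6 and 3 lists in the last 3 comparisons. By construction it raises the fold changes of other genes where those mRNAs fell, though not each gene equally. The cause of the changed list counts, and of the 1 gene called in the last comparison, was not tested. Olfactory receptor scaling called 4472 genes in the first. Nuclear genes alone gave 0 lists after proteinase K and 1 list in mitoplasts against IP_RNase, since the mitochondrial lists were removed. They gave 15 genes after proteinase K, where 13 of the 37 calls were mitochondrial, and the cause of the further loss was not tested. Fits of the 6 compared libraries called 143, 115 and 11 genes in the last 3 comparisons, and the cause was not tested. The test against a log2 fold change of 1 called 184, 0 and 0 in the first 3 (edgeR, with 4738, 2346 and 2365 genes at an unadjusted p under 0.05 against no change). The estimated correlation left 1, 1 and 0 lists in the last 3 comparisons. A minimum count of 50 gave 3 lists in the last comparison. Leaving out crude_RNase 2 with IP_RNase 3 gave 6 genes in the last comparison and 1 and 3 lists after proteinase K and in the last, and the cause was not tested. The mitochondrial share difference in the first comparison was -34.5 points as mitochondrial mRNA of protein-coding counts. It was -30.8 as mitochondrial mRNA of counts without nuclear rRNA genes and without ENSRNOG00000043866 and ENSRNOG00000030478, which were taken as the mitochondrial rRNAs.

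Leaving out each library gave 1198 to 1966, 24 to 88, 25 to 78 and 0 to 2 genes, and 14 to 15, 2 to 4, 2 to 4 and 0 to 2 lists. The share differences ranged from -47.1 to -40.8, -5.35 to -1.56, -4.82 to -1.02 and 0.192 to 0.919 points. The replicate numbers showed no pairing of the samples: 0 of 18 same-number pairs of deviations correlated over 0.1 (-0.172 to 0.099) and 0 of 12 libraries correlated best with their own number in every other group. Counting noise could hide a weak pairing, so pairing is not excluded. With the replicate block 1638, 33, 41 and 0 genes were called (edgeR, 741 in the last at an unadjusted p under 0.05), 14, 2, 4 and 1 lists passed, and the share differences were -43.0, -3.77, -3.23 and 0.536 points. The block brought the sarcomere list past the camera threshold in mitoplasts against IP_RNase (adjusted p = 0.0417) and ended the call of Mt-co1 there (edgeR adjusted p = 0.0706).

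Among values called with or without the change of scaling, signs that changed under library size alone in the first comparison were those of Mrps21 (0.20), Hspa5 (0.23), Cd74 (0.32), Plin4 (0.40), Hba-a2 (0.44), Sdc4 (0.38) and Mylk (0.68), less than the shift of 1.03 of the all-gene median. Under mitochondrial mRNA scaling, with a shift of 3.81, they were those of Tnni2 (0.12), Ckm (0.36), Pygm (1.12), Rplp0 (0.68), Rps6 (1.21), Col3a1 (0.55), Col1a1 (1.72), Sparc (1.21), Vdac3 (2.63), Atp5f1b (1.11), Cox4i1 (2.13), Casq1 (2.06), Ckmt2 (2.42), Mrps21 (2.93), Hspa5 (3.02), Cd74 (3.14), Mt-nd6 (0.53), Mt-atp8 (0.97), Plin4 (3.21), Fabp4 (2.72), Hba-a2 (3.2), Sdc4 (3.13), Mylk (3.50) and the 5S_rRNA copy ENSRNOG00000034597 (1.98). The same scaling turned Mt-nd6 (0.085), Mt-atp8 (0.39) and ENSRNOG00000069946 (0.0499) after proteinase K, and Mt-co1 (0.048), Mt-atp6 (0.15), ENSRNOG00000043866 (0.59) and ENSRNOG00000030478 (0.79) in mitoplasts against IP_RNase. It also turned the camera direction, relative to other genes, of the mitochondrial ribosomal proteins (adjusted p = 0.968), the noncoding RNAs reported in mitochondria (4.97e-23), the nuclear-retained RNAs (8.35e-92) and the small nucleolar RNAs (1.08e-46) in the first comparison, of the noncoding RNAs reported in mitochondria after proteinase K and in mitoplasts against IP_RNase (0.000175 and 0.00147), and of mitochondrial rRNA and tRNA in the latter (0.541). That last list also turned without IP_RNase 3 (camera adjusted p = 0.942, the highest of the fits without 1 library, the lowest being 5.59e-08 without IP_RNase 2) and without IP_RNase 3 and crude_RNase 2 (0.94), and the cause was not tested.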

Other observations

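The tests in this part were chosen only after the result was seen, except that the fit without IP_RNase 3 and the counts of genes and lists called by edgeR, DESeq2 and camera were planned.

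Some differences in the mitochondrial and sarcomeric transcripts stand apart from the comparisons. The ratio of Mt-nd6, encoded on the other mitochondrial strand than the remaining mRNAs, to Mt-co1 was 0.0875 to 0.101 in the 3 crude_RNase libraries and 0.152 to 0.213 in the other 9. The counts of the 2 abundant genes of the mitochondrial rRNA and tRNA list relative to mitochondrial mRNA were 0.797, 0.849 and 1.14 in crude_RNase, 0.369, 0.302 and 0.955 in IP_RNase, 0.380, 0.653 and 0.620 in IP_RNase_ProK, and 1.09, 0.840 and 0.667 in mitoplast_RNase. Ttn, the largest sarcomeric protein, had 52393 counts in crude_RNase 2 against 9936 and 11829 in the other crude_RNase libraries, and Neb, the thin filament ruler, had 6159 against 2661 and 2628. In mitoplast_RNase 2 the count of Ttn was 13134, against 8262 and 6210 in the other mitoplast libraries.

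Genes that muscle is not known to transcribe had counts in every library. Reads shared between paralogs alone are argued against by the median of 27 genes specific to other tissues, such as Alb of liver, Gfap of brain and Umod of kidney, which was 152 or more in each library. Low-level muscle RNA cannot be told apart from other sources by these genes: 100% of them had at least 10 counts in each library, but so had 96.0% to 98.3% of the olfactory receptor genes on which the pattern was seen, so the outcome was fixed beforehand. Nuclear genomic DNA in the libraries may account for the pattern, since in 11 gene families the X-linked members had at most 0.455 times (0.402 to 0.455 over the 12 libraries) the counts of autosomal members in this male animal, which carries 1 X chromosome and 2 copies of each autosome. RNA made in proportion to gene copies would give such a ratio too. The labels state a DNase step, the source of the counts was not measured directly, and no biological explanation was tested.

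Mitochondrial mRNAs were lower after proteinase K and in mitoplasts than after immunoprecipitation alone. IP_RNase 3, which had the highest mitochondrial share of its group, is argued against as the whole cause: without it the medians were -0.85 in both comparisons, with 12 and 10 of 13 still called lower by edgeR. Mitochondrial DNA as the source of all mitochondrial reads cannot be told apart from RNA. The ratio of the 2 abundant genes of the mitochondrial rRNA and tRNA list to mitochondrial mRNA varied 3.61 times over the 9 libraries. If these genes are rRNAs, however, the depletion step acts on them, IP_RNase alone spanned 0.302 to 0.955, and the ratio of Mt-nd6 to Mt-co1 varied 1.41 times. A larger share of background counts per unit of RNA cannot be told apart from lower mitochondrial RNA, because the 35 nuclear genes far lower after immunoprecipitation (median change -0.048 after proteinase K and 0.02 in mitoplasts) had a median of 70.7 counts in IP_RNase, close to the 40 of olfactory receptor genes. Loss of RNA with the outer membrane or with surface proteins stays open and untested.

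A set of 11 unnamed genes outside the 37 mitochondrial ones was called lower together with the mitochondrial mRNAs in both comparisons, with medians of -1.05 and -1.07. Reads of mitochondrial RNA counted in these genes are argued against: their median between IP_RNase and crude_RNase was -0.38 (-1.25 to 0.53), while that of the mitochondrial mRNAs was -3.69. Overlap of these genes with nuclear copies of mitochondrial DNA was not analysed here, so reads of mitochondrial DNA counted in them stay open. What else these genes share was not analysed here, and no biological explanation was tested.

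The 6 libraries of each comparison can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The numbers of genes called by edgeR in the real split and the highest of the other splits were 1684 and 0, 37 and 4, 41 and 5, and 0 and 1 in the 4 comparisons in the order of the report, and 1, 1, 1 and 10 of the 10 splits called as many as the real one. For the count of 0 in the last, 741 genes had an unadjusted edgeR p under 0.05 and DESeq2 called 0. For lists past the camera threshold the values were 14 and 12, 2 and 2, 3 and 3, and 1 and 3, and 1, 6, 4 and 6 of the 10 splits gave as many. Each of the other splits keeps 2 libraries of 1 group together, so part of any group difference stays in it. Regrouped libraries gave up to 12 lists in the first comparison, which therefore cannot show how many lists pass without a group difference. The splits do not settle how far passing the threshold reflects one.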
